A study of Mus musculus with 2 samples.

How the data were processed

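Total RNA was profiled on 2 single-channel oligonucleotide arrays, 1 of grafted mouse small intestinal epithelium and 1 of control mouse colonic epithelium. Per the labels' protocols, small intestinal cells of an EGFP-transgenic C57BL6 mouse were grown for 7 days as organoids, which are stem cell-containing epithelial cultures, and were placed in the colonic lumen of recipient C57BL6 mice. The graft was collected 4 weeks later, and both epithelia were cut from tissue sections by laser microdissection. Per the labels' protocols, 4.33 ng of RNA per sample was amplified with a whole-transcriptome kit and labelled with biotin, and the series' design text says that the graft and the colon sample with the highest RNA integrity were chosen for the arrays. Such amplification of small amounts of RNA can distort the levels of single transcripts, and its error cannot be measured with 1 array per group.

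The table deposited by the authors holds 1 log2 expression value per probe set and array, for 24074 probe sets. The software, background correction and normalization behind these values are not given in the sources used here. The scale was read from the values, which run from 4.19 to 13.37 on the graft array and from 4.22 to 13.46 on the colon array. A 16-bit scanner's range ends at 16 on a log2 scale, and natural or decimal logarithms of such a range would end below the highest values. The sorted columns differ by at most 0.25, so the 2 distributions were nearly the same, with medians of 5.44 and 5.43. Genes had not been centred over these 2 arrays, because centred values would mirror each other, whereas the arrays correlated with a Pearson r of 0.94 over all probe sets. Whether arrays had been centred stays unknown. The values are levels of a single channel, so no dye direction is involved. Exactly equal values on both arrays were found for 2910 probe sets, 12.1% of the table. No detection call comes with the values, so a level near the lower end cannot be separated from background, and a difference against such a level is understated by an unknown amount.

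Probe sets were named through the platform's annotation. A single gene symbol was given for 18904 probe sets, several symbols for 1330 and no symbol for 3840. The latter 2 kinds were left out of all gene results. The Entrez identifiers of 18837 of the singly named probe sets were found in the RefSeq gene table of assembly GRCm38.p6, and 0 symbols needed updating. That table was used for names only, and no coordinates are given because the build behind the array's probe sets is not given in the sources used here. Where a gene had several probe sets, the one with the highest mean of both arrays stood for it, which gave 17305 genes. A gene entered the counts if the higher of its 2 values reached the median of all gene values, 5.48, and 9392 genes did.

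All differences are the graft value minus the colon value on the log2 scale, without further normalization. With 1 array per group there is no residual degree of freedom, so no test of the condition was made and no p-value is given. Genes were counted at differences of at least 4-fold and at least 2-fold. Before the data were examined, 33 gene lists with 495 different genes were fixed, of which 428 were measured. For each list the median difference of its measured members was set against the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile among them describes these 2 arrays and says nothing about variation between animals. Genes named in the text were chosen by a rule fixed beforehand: the 15 genes with the largest difference in each direction, with at most 2 per gene family and no predicted genes; up to 4 members of each list with the largest absolute difference and up to 2 in the opposite direction; and 21 anchor genes, of which 20 were measured. Of the 180 genes so chosen, 16 from lists of other cell types, ribosomal proteins and Paneth niche signals are covered in the main results only by their lists. Genes outside the rule were chosen after their values were seen. The remaining anchor is not reported here.

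The number of arrays limits the precision of every value. The only measure of technical error in the table is the agreement of different probe sets of 1 gene. Over 585 genes whose 2 brightest probe sets both reached the median level, the difference between the graft and the colon array varied between probe sets with an SD of 0.48, and 95.7% of these genes agreed within 1 on the log2 scale, most of them genes with small differences. Of 9 genes at least 4-fold apart with a second probe set at the median level, the second probe set had the same direction for 9 and reached 2-fold for 6. This corresponds to an SD of 0.34 per probe set, and probes shared between probe sets would make it too small. The counting and list procedures were tested on simulated data with that error. A simulated log2 change of 1.5 passed the 2-fold threshold for 96% of 100 genes, and a change of 3 passed the 4-fold threshold for 100% of 100 genes. Among 9190 simulated unchanged genes, 0.413% passed the 2-fold threshold and 0% the 4-fold threshold. These rates hold for that error only. It leaves out variation between animals and any amplification error shared by all probe sets of a gene, so they are not error rates of the real counts. Of 100 simulated lists of unchanged genes, 6 lay outside the central 95% of their random lists. In the real data the control list of 16 general epithelial genes reached percentile 99.9 with a median of 0.30 and 0 genes differing by 2-fold. A percentile near 100 can therefore go with a small shift, and it has to be read with the median and the counts.

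The alternatives were the mean of all probe sets of a gene, no filter or a filter at the 75th percentile, centring on the median difference, quantile normalization, removal of a loess trend on intensity, a floor at each array's 20th percentile, several changes of list membership and 50 bins. Leaving out probe sets with exactly equal values was added after seeing the data. Calculations were done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6.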

Results

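Gene expression was compared between small intestinal epithelium that had been grown as organoids and grafted onto the mouse colon and normal colonic epithelium of a control mouse. The comparison addresses which expression features of the small intestine and of the colon are found in the graft 4 weeks after transplantation. The design has 1 array per group, so no difference has a replicate check, and every value below describes these 2 samples. Each gene group is given with its median log2 difference, graft minus colon, and with the percentile of that median among random lists matched on expression. The SD of a difference between probe sets of 1 gene, 0.48 on the log2 scale over 585 genes, is the only error available and leaves out variation between animals. No sample of ungrafted small intestine was analysed here, so a difference cannot be assigned to the tissue of origin or to the grafting.

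Of the 9392 genes that reached the median expression level, 103 (1.10%) were at least 4-fold higher in the graft than in the control colon and 129 (1.37%) were at least 4-fold lower. At a 2-fold threshold, 333 genes (3.55%) were higher and 533 (5.68%) were lower. Across these genes the arrays correlated with a Pearson r of 0.82, and genes are not independent replicates. The largest measured positive differences were those of Pla2g4c, a cytosolic phospholipase, which was 129-fold higher in the graft, the antimicrobial ribonuclease Ang4 (111-fold), the alpha-defensin Defa24 (102-fold) and the chitinase-like gene Chil4 (60.6-fold). Prap1, Clca4b and the lipase gene Pnliprp2 were higher by 5.39, 4.99 and 4.90 on the log2 scale. The largest measured negative difference was that of Car1, a colonic carbonic anhydrase, whose level was 4.51 in the graft and 11.74 in the colon, a 150-fold difference. The transglutaminase Tgm3 (60.9-fold), the cytochrome Cyp2c55 (49.9-fold), the lectin-like goblet cell protein Zg16 (45.5-fold) and the acute-phase gene Saa1 (44.9-fold) came next. Cyp2d34, Sycn, Selenbp1 and Hao2 were lower in the graft by 24.7-fold, 22.3-fold, 20.5-fold and 18.6-fold. Chil4, Clca4b, Saa1 and Defa24 have near-identical relatives whose transcripts can bind the same probes, so their values are uncertain as values of a single gene. On the colon array Pla2g4c (4.55), Defa24 (4.22) and Chil4 (4.31) lay below the array's 20th percentile of 4.74. On the graft array Car1 (4.51), Cyp2c55 (4.46), Cyp2d34 (4.55) and Hao2 (4.41) lay below that of 4.75. Signal cannot be separated from background there, so the folds and the order of such genes are not determined. The same limit holds for genes named below with a value under these percentiles.

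**Figure D1:**
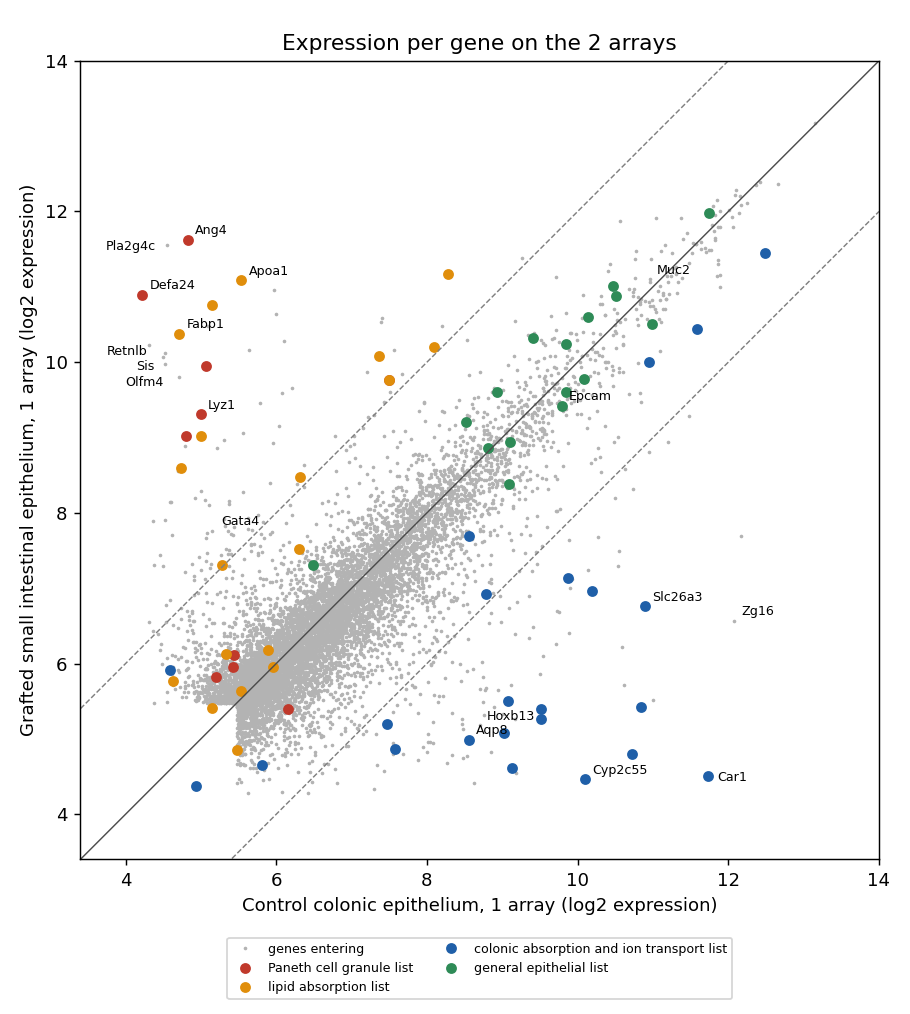
Each point is 1 gene, with its log2 expression on the colon array on the horizontal axis and on the graft array on the vertical axis. The solid line marks equal levels and the dashed lines 4-fold differences; coloured points are members of 4 gene lists, including members below the level that genes had to reach to enter. Ang4, Defa24 and Fabp1 lie near the lower end on the colon array, and Car1 and Cyp2c55 near the lower end on the graft array, while general epithelial genes lie close to the line.

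Paneth cells are the antimicrobial secretory cells at the base of small intestinal crypts. Genes for their granule proteins were higher in the graft as a group, whereas genes for their niche signals had a median near 0. Of 10 measured genes for Paneth cell granule proteins, 6 were at least 4-fold higher and 0 were lower by 2-fold, with a median log2 difference of 3.24, above all 10000 random lists. Besides Ang4 and Defa24, the lectin Itln1 was higher by 4.88, the lysozyme gene Lyz1 by 4.31 and the metalloproteinase Mmp7 by 4.22. Pla2g2f had a difference of -0.75. The median changed to 2.27 without Ang4 and to 4.22 without the genes that are also in other lists, and 15 of the 25 genes fixed for this list were not analysed here, most of them alpha-defensins. Paneth cell niche signals had a median difference of 0.077 (percentile 89.4), and 0 of 8 genes differed by 2-fold. Wnt3 had a difference of 0.16, Egf of -0.30, Dll1 of 0.51 and Cd24a of 0.39, and 5 of the 8 genes stayed below the median expression level on both arrays.

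Crypt stem cell genes had a median of 0.055 over 22 genes (percentile 91.8), with 2 at least 2-fold higher and 2 lower. Olfm4, a marker of small intestinal stem cells, was 34.0-fold higher in the graft, at 9.80 against 4.71. The adhesion receptor Cd44 was 3.49-fold higher. Lgr5, the Wnt target that marks cycling crypt stem cells, was 2.60-fold lower, at 5.10 against 6.47, and Aqp4 was 2.61-fold lower. Ascl2 had a difference of -0.12. Of 19 cell cycle genes, 0 differed by 2-fold, with a median of 0.036 (percentile 85.1). Mki67 had a difference of 0.23, Top2a of 0.48, Mcm7 of 0.39, Mcm4 of -0.39 and Pcna of -0.34.

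Absorptive enterocyte genes of the small intestine were higher in the graft in their lipid-handling part and went in both directions in digestion and nutrient transport. Of 19 genes for lipid absorption and lipoprotein assembly, 13 were at least 2-fold higher in the graft and 0 were 2-fold lower, with a median of 2.11, above all 10000 random lists. The fatty acid binding protein Fabp1 was 50.8-fold higher, the apolipoproteins Apoa4 and Apoa1 were 48.8-fold and 46.8-fold higher, the sterol transporter Npc1l1 16.2-fold and Fabp2 4.32-fold. Cd36 had a difference of -0.63. Among 14 brush-border enzymes of sugar and peptide digestion, 3 were at least 2-fold higher and 2 were lower, with a median of 0.29 that was also above all random lists and close to the 0.30 of general epithelial genes. Intestinal alkaline phosphatase Alpi was 48.6-fold and sucrase-isomaltase Sis 43.8-fold higher, and Akp3 2.85-fold. The metalloprotease Mep1a was 16.3-fold lower and Naaladl1 2.67-fold lower. Lactase, Lct, lay near the lower end on both arrays, at 4.92 and 4.64. Of 16 nutrient transporters, 5 were at least 2-fold higher and 4 lower, with a median of 0.42, again above all random lists. The amino acid transporter subunits Slc7a9 and Slc3a1 were 8.74-fold and 3.93-fold higher and the nucleoside transporter Slc28a2 4.19-fold. Slc36a1, a proton-coupled amino acid transporter, was 7.20-fold lower, and the peptide transporter Slc15a1 was 3.92-fold lower in the graft, at 7.48 against 9.45.

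Several regional transcription factors of the small intestine were higher in the graft, and several of those of the colon were lower. Of 10 factors of the small intestine, 5 were at least 2-fold higher in the graft and 0 were 2-fold lower, with a median of 0.88, above all random lists. That median was 0.40 without the genes that are also in other lists and 0.49 without Gata4. General epithelial genes had a median of 0.30. Gata4, which is expressed in the proximal small intestine, was 6.09-fold higher at 7.76 against 5.15, the duodenal factor Pdx1 4.21-fold, Creb3l3 4.09-fold and Onecut2 3.11-fold. Nr1i2 had a difference of -0.60. Of 9 factors of the colon and of posterior position, 3 were at least 4-fold lower in the graft and 0 were 2-fold higher, with a median of -0.81, below all random lists. The posterior homeobox genes Hoxb13, Hoxd13 and Hoxd10 were 11.4-fold, 8.46-fold and 4.26-fold lower. Hoxa13 had a difference of -0.84 and Hoxd12 of 0.16. Among 9 duodenal genes, 4 were at least 2-fold higher and 2 lower, with a median of 0.68 (percentile 99.99). The incretin gene Gip was 6.75-fold and the iron reductase Cybrd1 3.24-fold higher, while the iron exporter Slc40a1 was 4.66-fold and the calcium channel Trpv6 2.10-fold lower. Without the members that other lists hold, that median was -0.17. Of 9 ileal genes for bile acid and cobalamin uptake, 1 was 2-fold higher and 2 were lower, with a median of 0.046 (percentile 84.6). Slc51a was 4.57-fold higher and Slc51b had a difference of 0.53. The ileal bile acid genes Fabp6 and Slc10a2 were 2.49-fold and 2.16-fold lower in the graft.

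Colonic absorptive cell and ion transport genes were lower in the graft. This is a list for a cell type, and members such as the transglutaminase Tgm3 and the cytochrome Cyp2c55 are not transporters. Of 23 measured genes, 19 were at least 2-fold lower, 15 of these at least 4-fold, and 1 was 2-fold higher, with a median of -3.23, below all 10000 random lists. After Car1, Tgm3 and Cyp2c55, the largest differences were those of Ly6g (42.7-fold) and the amino acid transporter Slc6a14 (22.8-fold). Ggh was 19.0-fold lower, the chloride-bicarbonate exchanger Slc26a3 17.6-fold, the proton pump Atp12a 17.4-fold and the water channel Aqp8 11.8-fold. Car4, which is also abundant in the graft, was 2.23-fold lower at 10.44 against 11.59. Sptssb was 2.52-fold higher.

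**Figure D2:**
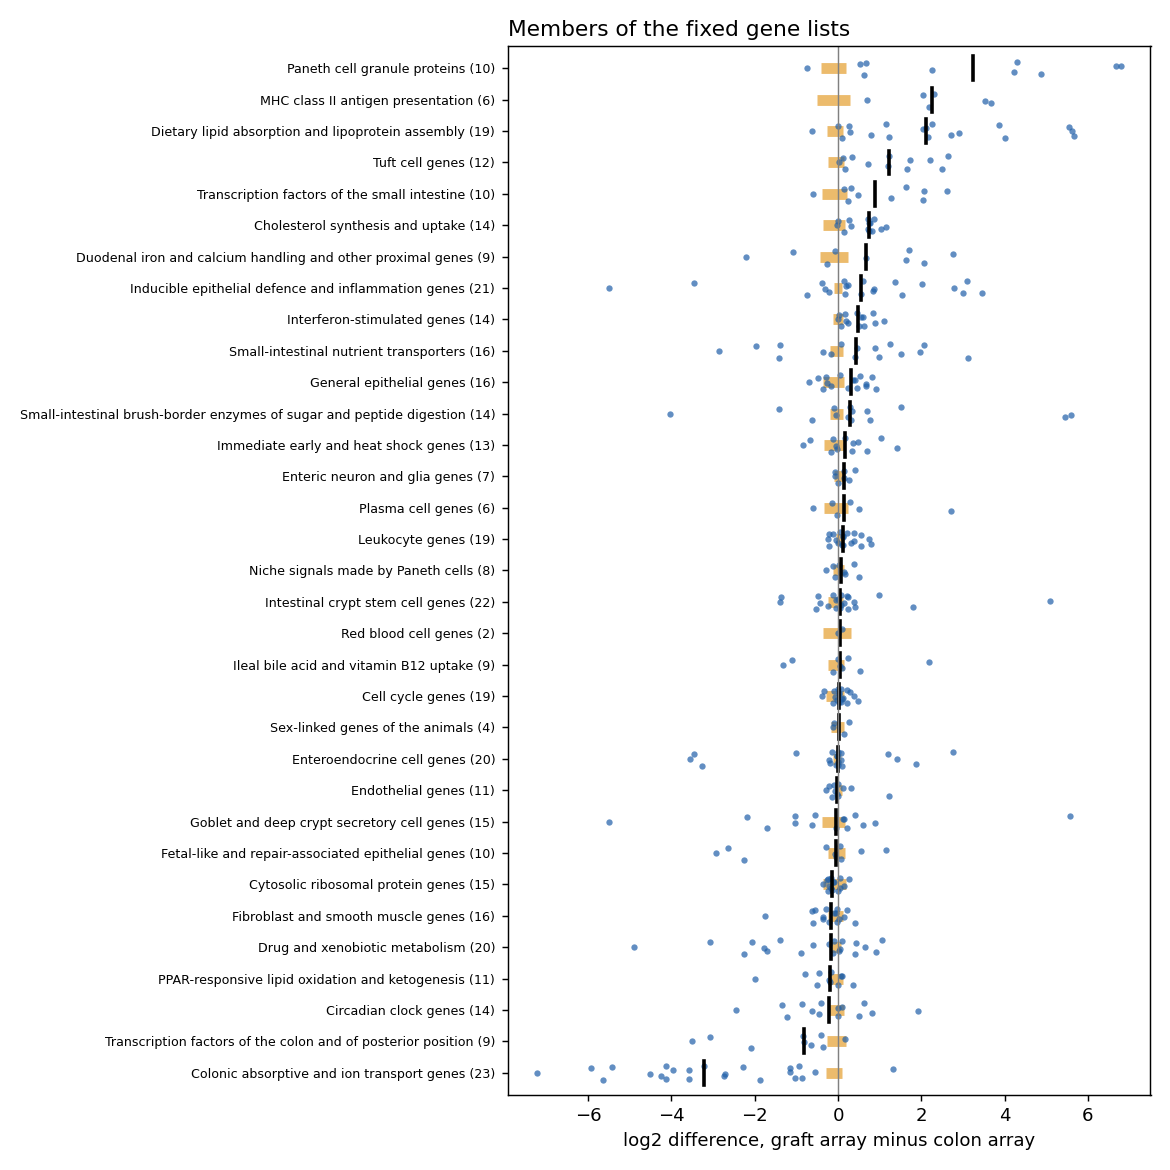
Each row is 1 of the 33 gene lists fixed before the data were examined, with the number of measured genes in brackets, and each point is the log2 difference of 1 member, graft array minus colon array. Black bars are list medians, and orange bands hold the central 95% of medians of 10000 random lists matched on mean expression. Paneth cell granule genes have the highest median (3.24) and colonic absorptive and ion transport genes the lowest (-3.23).

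Among the secretory lineages, tuft cell genes were higher in the graft, and goblet and enteroendocrine genes went in both directions. Goblet cell genes had a median of -0.043 over 15 genes (percentile 63.2), with 1 at least 2-fold higher and 5 lower. The main gel-forming mucin Muc2 had a difference of 0.14 and Spink4 of 0.88. Retnlb, a secreted bactericidal protein of goblet cells, was 47.6-fold higher in the graft, at 10.07 against 4.50, whereas Zg16 was 45.5-fold lower, and the channel Best2 and the chemokine Ccl6 were 4.53-fold and 3.24-fold lower. Of 20 enteroendocrine genes, 4 were at least 2-fold higher and 4 lower, with a median of -0.0092 (percentile 31.3). The hormones of the distal gut Insl5, Pyy and Gcg had differences of -3.55, -3.46 and -3.27, Gip was 6.75-fold and ghrelin, Ghrl, 3.67-fold higher, and the pan-endocrine granule gene Chga had a difference of -0.15. Of 12 genes of tuft cells, which are chemosensory cells, 7 were at least 2-fold higher and 0 were 2-fold lower, with a median of 1.22, above all random lists. Alox5ap was 6.25-fold, Rgs13 5.65-fold, Sh2d6 4.63-fold, Avil 3.32-fold and the tuft cell marker Dclk1 3.15-fold higher.

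MHC class II genes, which present antigen to T cells, were higher in the graft. Of 6 measured genes, 5 were at least 4-fold higher, with a median of 2.25, above all random lists. The invariant chain Cd74 was 12.8-fold, H2-Ab1 11.5-fold, H2-Eb1 4.96-fold and H2-DMa 4.57-fold higher. Leukocyte genes, measured in the same samples, had a median of 0.12 over 19 genes (percentile 99.3), and 0 differed by 2-fold. The pan-leukocyte gene Ptprc was higher by 0.78 and C1qb by 0.73, Gzma and Cd68 by 0.56 and 0.55, and Adgre1 and Ccl5 had differences of -0.23 and -0.21. Of the 19, 12 stayed below the median expression level on both arrays. Plasma cell genes had a median of 0.13 over 6 genes (percentile 91.0), with the immunoglobulin A heavy chain Igha 6.54-fold higher in the graft, Jchain at 0.29, Mzb1 at 0.49 and Ighm at -0.59. The direction for Ighm turned to 0.11 when its 3 probe sets were averaged. Interferon-stimulated genes had a median of 0.48 over 14 genes, above all random lists, but only Oasl2 passed 2-fold (2.16-fold), followed by Usp18 at 0.89, Zbp1 at 0.85 and Oas3 at 0.62. Of 21 inducible defence and inflammation genes, 7 were at least 2-fold higher and 2 lower, with a median of 0.55, above all random lists. The subunits of the epithelial hydrogen peroxide source, Duoxa2 and Duox2, were 10.9-fold and 8.60-fold higher, while Saa1 was 44.9-fold lower and the cytokine Il18 was 11.1-fold lower. The other 5 higher genes, chosen after their values were seen, were the secreted lectin genes Reg1 (7.96-fold), Reg3b (6.94-fold) and Reg3g (2.88-fold) and S100a8 (4.04-fold) and S100a9 (2.56-fold), which are abundant in neutrophils and other myeloid cells. Fetal-like and repair-associated genes had a median of -0.054 over 10 genes (percentile 26.0), with 3 at least 2-fold lower and 1 higher. Anxa3, Anxa1 and Il1rn were 7.61-fold, 6.20-fold and 4.81-fold lower, Krt7 was 2.20-fold higher and Ly6d had a difference of 0.56. Over the members that reached the median expression level, that median was -1.28.

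In metabolism, genes for cholesterol synthesis and uptake were higher as a group, with a median of 0.73 over 14 genes, above all random lists, although only Insig1 (2.21-fold) and Cyp51 (2.06-fold) passed 2-fold. Fdps and Idi1 had differences of 0.85 and 0.81, and Dhcr7 of -0.024, or 0.055 with quantile normalization. Drug and xenobiotic metabolism genes had a median of -0.17 over 20 genes (percentile 1.43), with 7 at least 2-fold lower and 1 higher, and a median of -1.14 over the members that reached the median expression level. The efflux pump Abcb1a was 29.9-fold, the carboxylesterase Ces2a 8.37-fold, Adh1 4.77-fold and Gstm1 4.22-fold lower. Cyp2c66 was 2.09-fold higher and Cyp2c65 had a difference of 0.90. PPAR-responsive lipid oxidation genes had a median of -0.19 over 11 genes (percentile 4.12). The lipid droplet protein Plin2 was 4.01-fold lower, while Cpt1a had a difference of -0.80, Acadm of -0.50, Acot2 of -0.45, Ehhadh of 0.36 and Pdk4 of 0.091.

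Genes that bear on the makeup and handling of the samples were also compared. Of 16 general epithelial genes, 0 differed by 2-fold, with a median of 0.30 (percentile 99.9). Krt18 had a difference of 0.91, Cdx2 of 0.82, Elf3 of 0.68, Cldn3 of -0.71, Lgals4 of -0.49 and Epcam of -0.37. Cytosolic ribosomal protein genes had a median of -0.14 over 15 genes (percentile 33.4), between -0.36 for Rps9 and 0.27 for Rps2. Fibroblast and smooth muscle genes had a median of -0.16 over 16 genes (percentile 7.83). Of these, Lum was 3.38-fold lower in the graft, Dcn, Acta2 and Pdgfra had differences of -0.62, -0.60 and -0.54, and Col6a1 of 0.40. The endothelial list had a median of -0.020 over 11 genes (percentile 13.1), with Egfl7 2.34-fold higher and Pecam1 at -0.29. Of the 11, 9 stayed below the median expression level on both arrays. Neuron and glia genes had a median of 0.15 over 7 genes (percentile 97.0), all 7 below that level on both arrays. Red blood cell genes had a median of 0.053 over 2 genes (percentile 62.8), again all below it. Medians of such dim genes cannot show that these cells were equal in the 2 samples. Immediate early and heat shock genes had a median of 0.16 over 13 genes (percentile 97.0), with Atf3 2.65-fold and Hsph1 2.04-fold higher, Egr1 at 0.71, Ier2 at -0.84 and Jun at -0.66. Circadian clock genes had a median of -0.21 over 14 genes (percentile 3.79), with Nr1d1 5.49-fold, Dbp 2.55-fold and Nr1d2 2.35-fold lower, Nfil3 3.76-fold higher and Ciart at 0.82. Sex-linked genes had a median of 0.016 over 4 genes (percentile 62.5). Xist, the RNA of the inactive X chromosome of female cells, was at 8.86 in the graft and 8.60 in the colon, and the Y-linked genes Kdm5d, Eif2s3y and Uty lay between 4.44 and 4.81 on both arrays.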

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

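No test was made for this part, and the counts below were chosen after the data were seen. Probe sets outside the gene results also held large differences. Among the 3840 probe sets without a gene symbol in the annotation, 78 (2.03%) were at least 4-fold higher in the graft than on the colon array and 9 (0.23%) were at least 4-fold lower, whereas among the 18904 probe sets with a single gene 106 were higher and 136 lower. The largest positive difference in the whole table, 7.41, belonged to an unnamed probe set at 12.39 in the graft and 4.98 in the colon. Among the 1330 probe sets annotated with several genes, 12 were at least 4-fold higher and 2 at least 4-fold lower, with a largest difference of 4.25. These probe sets drew attention as a signal in data that the comparisons do not use, and no explanation was tested.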

How the results depend on the processing

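All 4 counts stayed within 1.5 times of the reported value under each of the 8 alternatives run: 99 to 110 genes at least 4-fold higher, 123 to 129 at least 4-fold lower, 271 to 360 at least 2-fold higher and 447 to 534 at least 2-fold lower. The last of the 8, leaving out probe sets of equal value, was chosen after seeing the data. Centring, quantile normalization and loess moved the median of the genes that entered by 0.047 to 0.053, and the share of higher genes at 2-fold from 38.5% to at most 42.4%. Of the list medians, 290 alternative values moved by less than 1.5-fold, within which medians near 0 can change sign. Leaving out genes in over 1 list turned the duodenal list to -0.17 and moved the Paneth granule list to 4.22, and leaving out its largest member moved the latter to 2.27, both by having fewer members. Keeping only members at the median expression level moved the fetal-like list to -1.28 and the xenobiotic list to -1.14, by leaving out dim genes. With 50 bins, 1 list percentile moved by over 5 points, that of the ribosomal protein genes, to 20.7. Of the 180 genes chosen by the rule, 3 had another sign under an alternative: Ighm, at 0.11 with all its probe sets averaged, and Dhcr7 and Slc4a1, which lay near 0, with quantile normalization (0.055 and -0.0011) and loess (0.047 and -0.012); the cause was not tested. No replicate could be left out. No paired analysis was possible because each group has 1 array. A pseudocount was not needed for values already on a log scale. Signal over background limits the genes near 4 to 5, where a difference is compressed and an absent transcript cannot be told from a weak one.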

Other observations

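Further genes, chosen after their values were seen, also differed between the graft and the colon. The chemokine Ccl25, which draws lymphocytes to the small intestine, was 12.7-fold higher in the graft, while Ccl28, a mucosal chemokine of the colon, was 5.41-fold lower. Of 8 tight junction claudins that reached the median expression level, 2 were at least 2-fold higher and 3 lower, with a median of -0.40. Cldn15 was 3.01-fold and Cldn4 2.85-fold higher, and Cldn8 was 9.09-fold, Cldn23 2.16-fold and Cldn12 2.10-fold lower. The mitochondrial urea cycle enzyme Cps1 was higher by 4.65 on the log2 scale, arginase Arg2 9.74-fold, the purine enzymes Ada and Enpp3 11.4-fold and 12.5-fold, and malic enzyme Me1 14.5-fold. The sulfate transporter Slc13a1 was 11.7-fold higher, whereas Slc5a8, a transporter of short-chain fatty acids, was 10.5-fold lower.

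Gene families of oxidation, reduction and sulfation enzymes, picked after their values were seen, were counted without a test. Of 24 cytochrome P450 genes that reached the median expression level, 9 were at least 2-fold lower in the graft and 2 higher, against 533 and 333 among all 9392 genes. Cyp2d12 and Cyp2c68 were 7.78-fold and 7.24-fold lower. Of 9 hydroxysteroid dehydrogenase genes 4 were at least 2-fold lower and 0 higher, with Hsd3b3, Hsd17b2 and Hsd11b2 at 12.1-fold, 8.13-fold and 5.37-fold. Of 8 aldo-keto reductases 4 were at least 2-fold lower and 0 higher, with Akr1c14 and Akr1c19 at 6.57-fold and 6.29-fold. Of 13 aldehyde dehydrogenases 3 were at least 2-fold lower and 1 was higher, with a median of -0.41. Of 6 sulfotransferases, 4 were at least 2-fold lower, led by Sult1a1 (12.8-fold) and Sult1d1 (11.2-fold), and Sult6b2 was 11.7-fold higher.

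In the weighing of patterns, the goblet cell, handling stress and time-of-day tests were chosen after the values were seen, and so was the rule that leaves a test of other cells undecided where at least 50% of its genes stay below the median expression level on both arrays. The time-of-day and goblet cell tests leave out the genes that make up their patterns. Intervals are 95% bootstrap intervals over genes, which are not independent replicates.

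MHC class II genes were higher in the graft, together with Cxcl9 at 17.0-fold and Ubd at 10.4-fold. Leukocytes are a candidate source that laser dissection reduces but need not remove: the median of 25 leukocyte genes not looked at before was 0.11 (0.043 to 0.35), below the limit of 1 that had been set beforehand for excluding them. That limit was wrong, because 16 of the 25 genes lay below the median expression level on both arrays. The other 9 had a median of 0.75, with 8 higher in the graft, among them Rac2 at 1.92, Srgn at 1.09, Lcp1 at 0.81 and Tyrobp at 0.78. Only the most abundant, Ctss, was lower, at -1.50. However, Fcer1g, Lcp1, Ly86 and Rac2 reached that level on the graft array only, so the filter fixed their sign. The median of these 9 genes is therefore not evidence for leukocytes. The myeloid genes S100a8 and S100a9 were higher by 2.01 and 1.36. Leukocytes stay open, because genes below the median expression level cannot decide the question. A wider interferon gamma response also stays open, since 20 of 24 further target genes were above 0 with a median of 0.56 (0.27 to 0.85), an interval that includes the limit of 0.58. Over the 23 of them that reached the median expression level the median was 0.61, for which no interval was made. Iigp1 was at 2.60, Tap1 at 1.70 and Psmb9 at 1.54, against Cxcl11 at 0.30, Cxcl10 at 0.16, Tap2 at -0.045, Tapbp at -0.23, Serping1 at -0.23 and Psme2 at -0.29. A difference between small intestine and colon was not tested and stays open.

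Retnlb, Chil4, Ang4, Pla2g4c and tuft cell genes were higher together in the graft. More goblet cells as the whole cause would raise goblet cell genes together. Of the 14 goblet cell genes other than Retnlb, 0 were at least 2-fold higher and 5 were lower, with a median of -0.30 (-1.03 to 0.21). The list also holds genes of deep crypt secretory cells, so its lower members are not counted as evidence. Of the 14 genes, 6 were above 0, with Spink4 at 0.88, Spdef at 0.59, Reg4 at 0.41 and the abundant Muc2 and Clca1 at 0.14 and 0.13. That 0 were 2-fold higher argues against more goblet cells as the whole cause. A smaller rise in goblet cells is not excluded. This test was chosen after the values were seen. A type 2 cytokine response of the epithelium may contribute and stays open: 16 further target genes, 8 of them below the median expression level on both arrays, had a median of 0.11 (-0.073 to 0.66), with Il4ra at 1.43, Socs3 at 1.09, Muc3 at -0.70 and Gfpt1 at -1.52. Mast cells and eosinophils, which laser dissection also reduces, stay open too, since 10 of their 12 genes lay below the median expression level on both arrays and the other 2 went both ways (Siglecf at 0.52 and Kit at -0.35), so that their median of 0.097 (-0.071 to 0.21), although below the limit of 1 set beforehand, cannot exclude them. Regional origin was not tested and stays open.

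The clock genes Nr1d1, Dbp and Nr1d2 were lower and Nfil3 was higher in the graft. A different time of day at dissection is a candidate explanation that stays open. Without these 4 genes, the median of 9 other genes in phase with Dbp minus that of 3 other genes in phase with Bmal1 was -0.29 (-0.96 to 0.96). In the Dbp set, Usp2 was at -0.89, Per3 at -0.61, Per2 at 0.11 and Ciart at 0.82. Ciart lay below the median expression level on both arrays, and its second probe set had a difference of 0. The Bmal1 set held Clock at -0.86, Arntl (Bmal1) at -0.0040 and Cry1 at 0.51. For handling stress, the immediate early and heat shock genes had a median of 0.16 (-0.11 to 0.48). The upper end lay below the limit of 1, which was chosen after the values were seen. That limit applies to a rise of all members together. The members went both ways, with Atf3 at 1.41 and Hsph1 at 1.03 against Ier2 at -0.84 and Jun at -0.66. The median therefore cannot exclude a response of some members, and handling stress stays open too.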
